A study of Homo sapiens with 5 samples.

How the data were processed

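The data are RNA sequencing profiles of human embryonic stem cells before and during neural differentiation in floating culture, with or without trichostatin A (TSA), an inhibitor of histone deacetylases, at 10 ng/ml. There were 5 groups with 1 library each: undifferentiated cells (day 0), untreated cells at day 4 and at day 8, cells at day 4 that had TSA over days 0 to 4, and cells at day 8 that had TSA over days 4 to 8. Total RNA was extracted with Trizol and libraries followed a standard Illumina protocol, per the labels. The titles of the untreated day 4 and day 8 samples name H9, an established human embryonic stem cell line. The labels of the day 0 and TSA samples used here do not name a line. With 1 library per group there is no spread between replicates, so no p-value or standard deviation is given and no difference between groups was tested against replicate error. Every difference is one between 2 libraries.

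The deposited table holds log2 values per gene, with the locus number and symbol that a Cufflinks assembly gives. Per the submitters' processing notes the tools were TopHat2 2.0.4 (alignment), Cufflinks 2.0.2 and Cuffdiff 2.0.2, on the human build hg19. Their settings, the read type and the number of reads are not given in the sources used here. The deposited log2 values were read as log2(abundance + 1), with abundance taken as FPKM, an abundance scaled to transcript length and to the number of mapped fragments. That unit is inferred from the tools and from the values, which start at 0 and reach 13.96, since no header states it. The table has 14751 genes and 8063 blank rows. The smallest row maximum was 1.00016 on the log2 scale, so the authors kept genes with an abundance of at least 1 in some library. Rows whose symbol occurs more than once number 155 and 21 symbols had been turned into dates. They stayed in the counts and are not named. The column headed H8/D8 was used for the untreated day 8 sample, titled H9/D8, because its day and lack of treatment match no other group.

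Depth is unknown. Ratios of low values between libraries showed no steps of whole reads: the fullest bin of 0.1 log2 units held 7.41 to 21.1% of the 5 to 128 genes below 0.15 in both libraries. No counting interval can be given, and small values of single genes are the least certain. The summed abundance was 375751 at day 0, 568840 and 511144 in the untreated day 4 and day 8 libraries, and 545979 and 459789 with TSA at day 4 and day 8.

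A log2 difference is the difference of the deposited values of 2 libraries, with the pseudocount of 1 that they carry, which understates the change of low genes. Genes with an abundance of at least 1 in the higher library were compared, and a gene was called by size alone, at 2-fold or more on that scale. The verbs rose and fell are used only of genes called in this way. The main comparisons were day 4 against day 0, day 8 against day 4, and TSA against untreated at day 4 and at day 8. Day 8 against day 0 was secondary. Genes named are the 6 largest increases and 6 largest decreases per main comparison among unique symbols with an abundance of at least 5 in the higher library (small RNAs, XIST and Y-linked genes left out), the 2 members of each gene list with the largest difference, and in every library POU5F1, NANOG, SOX2, PAX6, SIX3, CDKN1A and H1F0. SOX1 was also on that list and is not analysed here. A few genes that meet the rule are not reported here. Other list members are named to complete a count of called members, and the largest differences with genes that hold a small RNA left aside are also named. Both were decided after their values had been seen.

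The 32 gene lists with 373 members, of which 296 are in the table, were fixed with the comparisons, the floor, the fold threshold, the rule for named genes and the first group of alternatives below before the data were examined. For each list the median log2 difference of the members above the floor is given. Where a list had 3 or more such members, the median was ranked among 10000 random lists of the same size matched on mean expression in 20 bins. This rank describes these libraries and is no test. A list is called outside the central 95% when its median lies in the outer tails of the random lists. The TSA effects at day 4 and day 8 use 4 different libraries and were set against each other across genes, which are not independent replicates. Genes that differed over differentiation were defined on libraries that the TSA comparison did not use, and the interval of a median over genes is an order-statistic 95% interval over genes, not over cultures.

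Transcript length and GC content (the longest transcript per symbol) and the microRNAs and small nucleolar RNAs inside genes on the same strand came from GENCODE release 29. Older symbols were matched through the synonyms of the RefSeq gene table of GRCh38.p14. That annotation is on another build than the deposited table, so it served for names, lengths and which small RNA lies in which gene, and no coordinates are given. A length was found for 14281 genes (96.8%). There were 442 rows of small RNA genes, and 1028 genes held a small RNA. The alternatives set beforehand were pseudocounts of 0.1 and 5, no filter, a floor of 5, the median difference set to 0, trimmed mean scaling (30% of log ratios and 5% of log means trimmed at each end), and fold thresholds of 4 and 1.5. Removal of a trend with transcript length or with GC content, and leaving out small RNA genes and genes that hold one, were added after the data had been seen.

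The computation was tested on simulated data. With noise added to the day 4 library over 14751 genes, 95% of genes seeded with a log2 change of -1.5 and 100% of those seeded with 1.5, 2, 3 or -2 were called, as were 0.0311% of unchanged genes above the floor. The noise had a chosen size, equal at all expression levels, and changes were seeded only in genes well above the floor. No replicate shows the real size, so these shares check the computation and give no error rate for these libraries. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.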

Results

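Gene expression was measured by RNA sequencing in human embryonic stem cells at day 0 and in the cells they gave at days 4 and 8 of floating neural differentiation, without TSA or with TSA over the 4 days before collection. Each of the 5 groups had 1 library and there were no replicates. Abundances are given as deposited, on the log2(abundance + 1) scale, for 14751 genes. The number of genes with an abundance of at least 1 was 12502 at day 0, 12827 and 12967 in the untreated day 4 and day 8 libraries, and 13117 and 13551 with TSA at day 4 and day 8.

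POU5F1 (XLOC_026537), a core transcription factor of pluripotency, stood at 9.06 at day 0, 9.55 at day 4 and 7.77 at day 8, and with TSA at 9.38 at day 4 and 5.96 at day 8. NANOG, which acts with it, stood at 5.37, 5.14 and 2.89 without TSA and at 5.98 and 1.91 with TSA. SOX2, shared by pluripotent cells and neural progenitors, went from 6.62 to 6.91 and 7.38, with 6.77 and 6.62 under TSA. PAX6, a transcription factor of early neuroectoderm, went from 0.16 to 0.56 and 2.93, with 0.66 and 3.89 under TSA. SIX3, which marks the anterior forebrain and eye field, was listed at 0 at day 0 and reached 3.06 and 6.40, with 2.45 and 3.78 under TSA. The cell cycle inhibitor CDKN1A, often induced by inhibitors of histone deacetylases, stood at 3.22, 3.43 and 3.47, with 3.07 and 4.45 under TSA. H1F0, the linker histone H1.0, stood at 4.40, 6.33 and 7.44, with 6.97 and 7.70 under TSA.

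**Figure D1:**
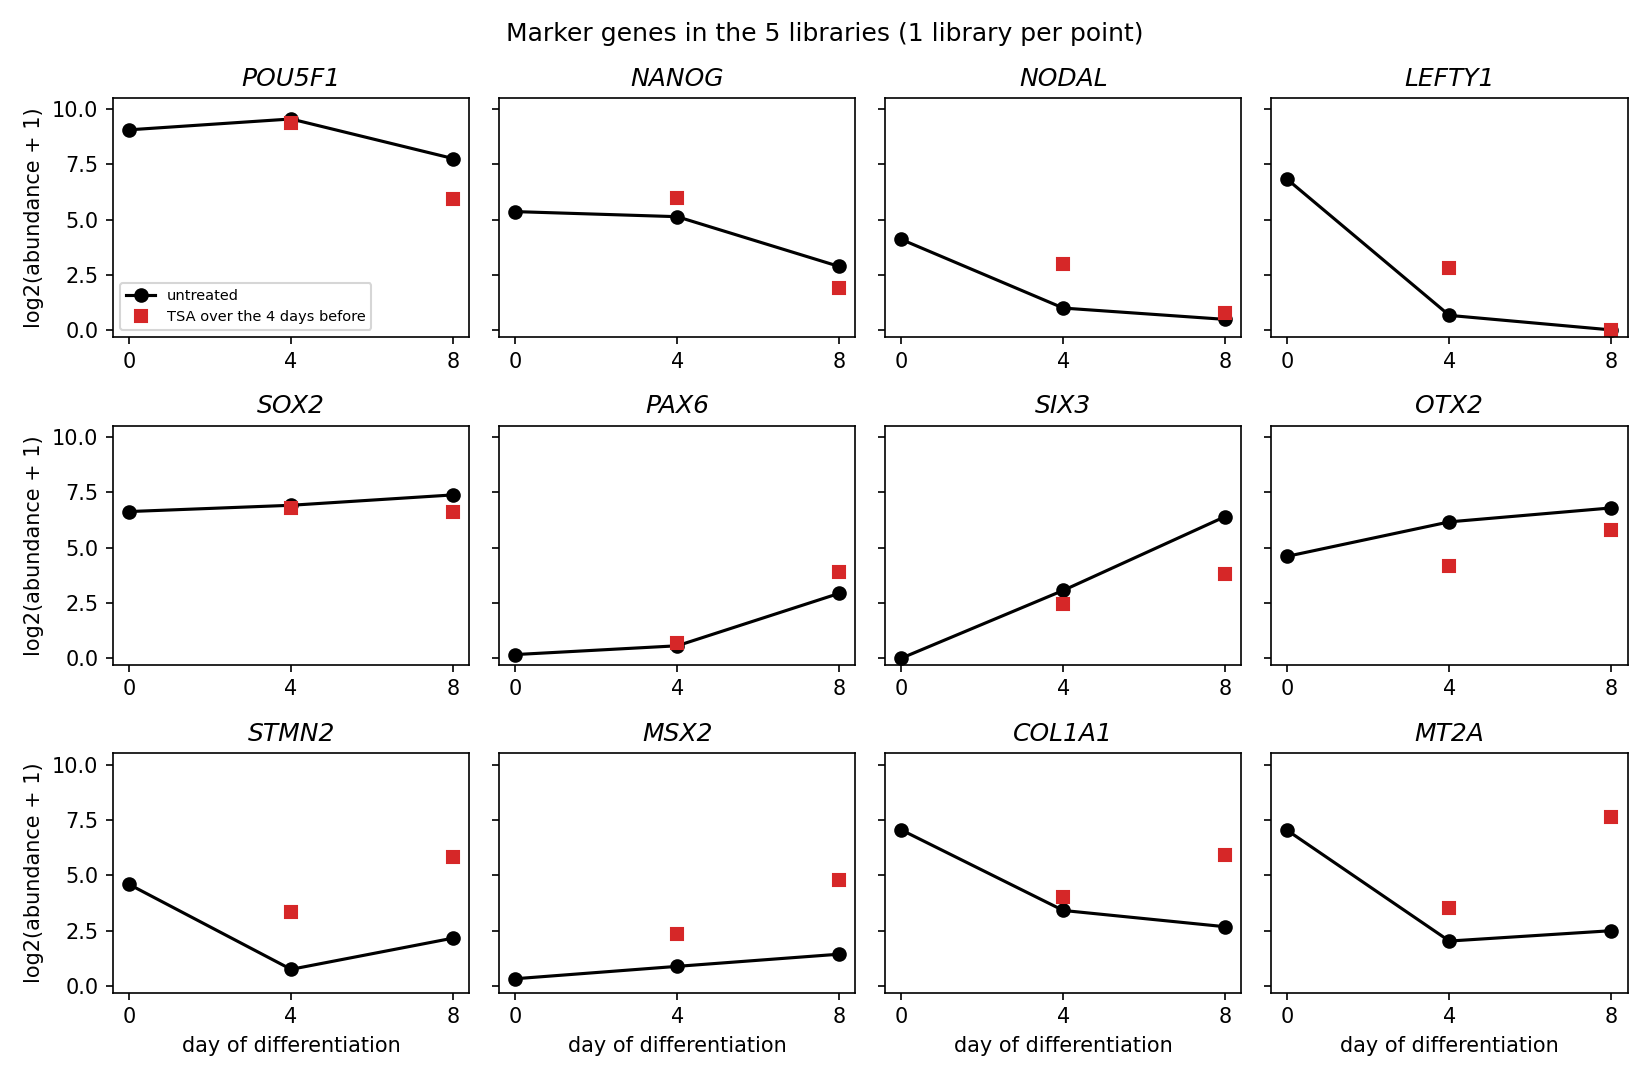
Abundance of 12 marker genes on the log2(abundance + 1) scale (vertical axis) against the day of differentiation (horizontal axis). Black circles joined by a line are the untreated libraries and red squares the libraries with TSA over the 4 days before, with 1 library per point. LEFTY1 stood at 2.84 with TSA against 0.68 without at day 4, and POU5F1 at 5.96 against 7.77 at day 8.

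The day 0 library stood apart from the other 4. Its Pearson correlation across genes with them was 0.733 to 0.796, against 0.894 to 0.945 among the other 4, and without small RNA genes the values were 0.802 to 0.868 against 0.916 to 0.973. Of 442 rows of small RNA genes, 290 were listed at 0 at day 0 (65.6%), against 114 to 157 in the other libraries. Small RNA genes made up 1.18% of the summed abundance at day 0 and 15.05 to 18.8% in the others. Ribosomal protein genes had a median of 8.98 at day 0 and of 10.40 to 10.75 in the others. The difference of day 4 from day 0 also followed transcript length: across genes the Spearman correlation was -0.48, with a median of 0.84 for the shortest 10% of transcripts and -0.62 for the longest, while that of day 8 against day 4 was 0.06. These values stand beside every comparison with day 0.

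The first comparison asked what differed as undifferentiated cells entered differentiation, day 4 against day 0. Genes of the forebrain and eye field list rose, and many genes of the Nodal, metallothionein and mesenchyme lists fell, while most pluripotency genes differed by less than 2-fold. Of 11 genes of the forebrain and eye field list in the data 6 were above the floor, and these 6 rose, with a median log2 difference of 2.66. With the trend with transcript length or with GC content removed, RAX differed by 0.99 or 0.59 and the other 5 were still called. LHX5 went from 0.10 to 3.70 and HESX1 from 1.26 to 4.69, both homeobox genes of the anterior neural plate. OTX2, FEZF1 and RAX rose as well, and SIX3 was listed at 0 at day 0. Of 8 genes of the Nodal and activin list, 5 fell and FOXH1 rose, with a median of -2.36. The Nodal antagonists fell most: CER1 from 7.84 to 0.23, LEFTY2 from 7.01 to 0.46 and LEFTY1 from 6.82 to 0.68.

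Of 18 pluripotency genes, FGF4, UTF1 and KLF4 rose, PODXL fell and 14 differed by less than 2-fold, with a median of 0.18. All 7 metallothioneins, which bind zinc and copper, fell, with a median of -3.46. MT2A went from 7.02 to 2.03 and MT1H from 5.98 to 0.92. In the mesenchyme list 5 of 9 genes fell and none rose, with a median of -2.54. Whether the day 0 cells grew on feeder cells is not given in the sources used here, and the falls of mesenchyme and metallothionein genes are differences from that library. VIM, an intermediate filament gene, went from 9.33 to 5.02 and COL1A1, a fibrillar collagen gene, from 7.05 to 3.41. CAV1 (7.32 to 0.84) and SPP1 (9.58 to 3.02) were also among the 6 largest decreases. Among targets and feedback inhibitors of FGF and ERK signalling 5 of 8 fell, DUSP6 by 2.85 and SPRY4 by 2.48 on the log2 scale, and the list's median was -1.20.

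In the neural progenitor list 3 genes rose (ZNF521, POU3F1 and FABP7) and 3 fell (CDH2, SOX3 and NES), with a median of 0.54. The 3 that rose were below 2-fold with a pseudocount of 5, ZNF521 at 0.69, POU3F1 at 0.58 and FABP7 at 0.36. In the neuron list 5 of 8 fell and none rose, with a median of -1.33: STMN2, a regulator of microtubules in growing axons, went from 4.59 to 0.75 and SYT1 from 4.19 to 2.43. Of the 13 targets of the neuronal repressor REST, 3 fell, among them VGF by 4.14, and the median was -0.69. BMP signalling genes moved apart: ID1, ID2, ID3 and BMP4 rose while SMAD7, BAMBI and BMP2 fell, and their median was 0.34. Retinoid genes had a median of 0.49, with CRABP1 and CRABP2 higher by 2.07 and 2.004. Cholesterol synthesis genes had a median of -0.78, with LSS among those that fell. Glycolysis and hypoxia genes had a median of -0.76, with SLC2A1 lower by 2.29.

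The median was 0.41 for 20 cell cycle genes, of which PCNA rose. Of 11 p53 response genes BAX (by 2.10), BBC3 and SESN1 rose and GDF15 fell by 1.69, with a median of 0.21. The median was 0.46 for 11 histone deacetylase genes, of which HDAC10 rose by 1.52 and HDAC9 fell by 2.03. For 8 histone acetyltransferase genes it was -0.24. The medians were -0.53 for endoplasmic reticulum stress, -0.31 for immediate early and heat shock, and -0.08 for Notch signalling. They were -0.25 for WNT signalling and 0.05 for housekeeping genes. Of 12 housekeeping genes 3 rose and none fell, and of 7 Notch genes 2 rose and 1 fell. In the endoplasmic reticulum stress, immediate early and heat shock, and WNT lists 1 gene each fell and none rose. Few markers of other lineages were above the floor: the medians were -0.34 for glia, 0.06 for neural crest, -0.18 for surface ectoderm, -0.57 for endoderm and -1.26 for trophoblast, over 3 to 7 genes each. The trophoblast median turned to 0.25 with no filter. The lists of mesoderm (0.17), germline (1.31), endothelium and blood (-1.30), and midbrain and hindbrain (-0.70) had 1 or 2 genes above the floor.

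In all, 1897 genes rose and 1669 fell among 13557 above the floor, and 226 of the genes that rose were small RNA genes. The counts were 1021 and 846 with a pseudocount of 5. Among the 6 largest increases were pseudogenes of ribosomal proteins, RPS10P7 (0.36 to 6.25) and RPS26P11 (0.37 to 6.16), and the mitochondrial rRNA-like copies MTRNR2L2 (2.20 to 8.69) and MTRNR2L8 (2.39 to 8.39), each a near copy of another expressed gene. RPL23P8 and NACAP1 reached 7.28 and 5.80 and were listed at 0 at day 0. Of 28 lists with 3 or more genes, 11 lay outside the central 95% of random lists. With the trend with transcript length removed, 1326 genes rose and 1454 fell, the histone deacetylase inhibitor response list went from a median of 0.93 (5 of 10 genes rose, TXNIP and H1F0 most) to 0.12, the retinoid list to 0.06, and 18 of 102 called list members were no longer called, among them CRABP1 (0.61), UTF1 (0.65), BMP4 (0.69), FABP7 (0.77), LSS (-0.96) and PCNA (0.27). Removing the trend with GC content ended 9 of these 102 calls, among them those of HDAC10 (0.88), UTF1 (0.86) and POU3F1 (0.82), and a pseudocount of 5 ended 32. List medians that changed sign were those of histone acetyltransferase (0.34), WNT (0.13), p53 (-0.08) and housekeeping (-0.14) genes with that trend removed, and of neural crest (-0.25) and Notch (0.08) genes with the GC trend removed. With a floor of 5 those of neural progenitor (-1.70), neural crest (-2.25) and immediate early and heat shock (0.64) genes changed sign, and with no filter those of neural progenitor (-0.02), glia (0.21), endoderm (0.07) and WNT (0.03) genes.

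The second comparison asked what followed from day 4 to day 8 without TSA. Most forebrain, eye field and neural progenitor genes above the floor rose, and some pluripotency genes fell. Of 10 forebrain and eye field genes 8 rose and none fell, with a median of 1.98. RAX, which specifies the eye field, went from 1.24 to 4.996, LHX2 from 0.49 to 4.12 and SIX3 from 3.06 to 6.40. Of 12 neural progenitor genes 9 rose and none fell, with a median of 1.54, PAX6 by 2.37 and the cadherin CDH2 by 2.24 on the log2 scale. Of 18 pluripotency genes 6 fell and none rose, with a median of -0.82: NANOG by 2.25, PRDM14 by 2.13, and FOXD3, POU5F1, L1TD1 and FGF4 by less. In the Nodal and activin list TDGF1, a co-receptor of Nodal, fell from 7.37 to 5.20 and GDF3 from 3.05 to 0.95, with a median of -1.31 over 4 genes.

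FGF8, a signal of the anterior neural ridge and of the midbrain boundary, rose from 0.65 to 4.08, and PAX2 reached 1.17 (median 2.27 over these 2 genes). In the neuron list 4 of 11 genes rose, MAP2 by 2.26, and GAP43 and TUBB3 fell, with a median of 0.43. REST targets had a median of -0.47, SCG3 lower by 1.75 and STMN2 higher by 1.41. Of the 7 mesenchyme genes TAGLN, COL6A1 and FN1 fell, with a median of -0.73. DLL1, a ligand of Notch, rose by 1.82 and HEY2 fell by 1.45. ETS1 fell by 2.66 in the neural crest list, whose median was 0.31. Outside the lists, DLK1 rose from 3.34 to 8.51, and with genes that hold a small RNA left aside ACTA1 (5.03 to 2.34), PDZD4 (4.19 to 1.51) and C9orf135 (4.67 to 1.95) were among the 6 largest decreases. The 6 largest increases of the fixed rule also had KIAA0226, H19, GABPB1-AS1 and LFNG, and the 6 largest decreases PLEKHM1P, ATF5, GPRC5A, CELSR3 and REXO1, and all of these hold a microRNA. NRF1, which also fell (6.50 to 2.91), does not.

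Among the remaining lists, the medians below 0 were -0.69 for endoplasmic reticulum stress, -0.67 for surface ectoderm, -0.55 for glycolysis and hypoxia, -0.52 for cholesterol synthesis and for WNT signalling, and -0.50 for immediate early and heat shock genes, with 0 to 2 called genes in each. Those of cell cycle (-0.40), housekeeping (-0.32), histone deacetylases (-0.21) and glia (-0.22) had 0 or 1 called gene. Medians above 0 were 0.48 for the histone deacetylase inhibitor response, of which HIST1H2BD, TXNIP and H1F0 rose, 0.41 for metallothioneins, 0.34 for retinoid genes, 0.31 for trophoblast, 0.29 for Notch signalling, 0.20 for FGF and ERK signalling, 0.16 for histone acetyltransferases, 0.12 for BMP signalling and 0.04 for the p53 response. The lists of mesoderm (0.39), endoderm (0.32), germline (0.01) and endothelium and blood (-1.86, KDR alone) had 1 or 2 genes above the floor.

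In all, 410 genes rose and 441 fell among 13451 above the floor, a share of 48.2% higher among the called genes. The median of all genes was -0.11, and the trimmed mean put the shift between the libraries at -0.13, so that with the median set to 0 the counts were 527 and 340 (60.8% higher) and with trimmed mean scaling 514 and 355 (59.1% higher). With a pseudocount of 5, 169 rose and 210 fell, and with one of 0.1, 748 and 729. Of the 62 called list members 24 differed by less than 2-fold with a pseudocount of 5. With a floor of 5 the medians of neuron (-0.62) and p53 (-0.11) genes changed sign, and with no filter that of WNT signalling (0.22). Of 27 lists with 3 or more genes, 16 lay outside the central 95% of random lists. Against day 0, the day 8 library had 2196 genes that were 2-fold higher and 2462 that were lower among 13856 (2467 and 2145 with the median set to 0, 2441 and 2212 with trimmed mean scaling), the forebrain and eye field median was 4.43 with 8 of 10 genes higher, the neural progenitor median 1.59, the Nodal median -2.88 and the mesenchyme median -3.05.

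The third comparison asked how TSA over days 0 to 4 altered the cells at day 4. Several Nodal pathway, neuron and metallothionein genes rose with TSA, the forebrain gene OTX2 fell, and none of the 18 pluripotency genes differed by 2-fold. In the Nodal and activin list NODAL itself (2.9985 against 1.01 without TSA), its antagonists LEFTY1 (2.84 against 0.68) and LEFTY2 (2.20 against 0.46) and the related ligand GDF3 (4.48 against 3.05) rose, FOXH1 fell by 1.02, and the median over 6 genes was 1.58. The FOXH1 difference was below 2-fold with the GC trend removed (-0.74), the length trend removed (-0.95), the median set to 0 (-0.96) and trimmed mean scaling (-0.97). NODAL, LEFTY1 and LEFTY2 stayed below their day 0 values of 4.11, 6.82 and 7.01, and GDF3 lay above its day 0 value of 2.27. The pluripotency list had a median of -0.16, with differences of 0.84 for NANOG and 0.90 for DPPA2 as its largest. In the forebrain and eye field list OTX2 fell from 6.16 to 4.16 and the other 5 genes differed by less than 2-fold, HESX1 by -0.88, with a median of -0.70.

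Of 10 neuron genes 6 rose and none fell, with a median of 1.08: STMN2 went from 0.75 to 3.35 and ISL1, a homeobox gene of motor and sensory neurons, from 0.59 to 1.95. REST targets had a median of 0.06, with STMN2, CHGA and SNAP25 higher. All 6 metallothioneins above the floor rose, MT1H by 2.08 and MT1F by 1.56, with a median of 1.41. In the neural crest list MSX2 (1.44), TFAP2A (1.37) and NGFR (1.11) rose among 6 genes, with a median of 0.80. In the mesenchyme list COL1A2 and FN1 rose among 8, with a median of 0.53. Of 17 genes of the midbrain and hindbrain list 4 were in the data and 3 above the floor (median 1.41). Of these FGF8 and GBX2 rose, and with a pseudocount of 5 they differed by 0.57 and 0.42, below 2-fold. HAND1 and GATA3 rose among 5 trophoblast genes (median 0.48) and SP5 and TCF7 among 5 WNT signalling genes (median 0.64). Of 8 genes of the germline list 3 were in the data, of which MAGEA4 and TDRD1 rose (median 1.03). In the neural progenitor list ZIC2 (-1.4995) and MSI1 fell and FABP7 rose, with a median of -0.22.

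Among 10 genes of the histone deacetylase inhibitor response GADD45B alone rose, by 1.07, and the median was 0.24. Of 8 endoplasmic reticulum stress genes ASNS (6.43 to 4.41) and CHAC1 (3.91 to 2.34) fell, with a median of -0.28. ASNS makes asparagine, and both are targets of ATF4. In the retinoid list CYP26A1, which breaks down retinoic acid, fell by 1.78 and RARB rose by 1.09, with a median of 0.37. B2M, the light chain of MHC class I, rose by 1.72 in the housekeeping list, whose median was -0.10. No gene was called among the histone deacetylases (-0.29), histone acetyltransferases (-0.29), cell cycle (-0.25), glycolysis and hypoxia (-0.31), cholesterol synthesis (-0.24), immediate early and heat shock (-0.15), surface ectoderm (0.15), endoderm (0.43) or mesoderm (0.33) genes, with medians in parentheses. One gene each rose in the lists of BMP signalling (0.29), FGF and ERK signalling (0.23), p53 response (-0.22), glia (-0.01) and Notch signalling (0.03). KDR was the 1 gene of the endothelium and blood list above the floor, and it rose by 1.65.

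In the table as a whole 392 genes rose and 222 fell with TSA at day 4 among 13499. The counts were 143 and 135 with a pseudocount of 5, and 725 and 357 with one of 0.1. DPPA5, a marker of early pluripotent cells, rose most, from 2.55 to 8.20. The chemokine CXCL5 went from 2.44 to 6.98 and CR1L from 0.73 to 4.86. The vault RNAs VTRNA2-1 and VTRNA1-3, short RNAs that the fixed rule did not leave out, stood at 5.24 and 4.48 with TSA and were listed at 0 in the other 4 libraries. KIAA0226 and TOMM40L, among the 6 largest increases, hold a microRNA, as do CELSR3, PLEKHM1, SFRP1 and C10orf118 among the decreases. NRF1 (6.50 to 2.79) and MFGE8 (7.47 to 5.35) do not. Without small RNA genes and genes that hold one, 285 genes rose and 97 fell. The difference between these 2 libraries followed GC content (Spearman -0.38 across genes, median 0.11 for the 10% of transcripts lowest in GC and -0.28 for the highest). With that trend removed, the medians were 1.74 for the Nodal list, 1.08 for neuron, -0.51 for forebrain and eye field, 0.01 for neural progenitor and -0.05 for histone deacetylase genes, and MSI1 (-0.99), SNAP25 (0.94), FAS (0.96) and TDRD1 (0.96) were no longer called. Of the 48 called list members 35 differed by less than 2-fold with a pseudocount of 5, among them NODAL (0.99), LEFTY1 (0.99) and LEFTY2 (0.67). In the neuron list DCX (0.43), MAP2 (0.45), ISL1 (0.51), SYT1 (0.86) and GAP43 (0.91) did so, which left STMN2. The 3 called neural crest genes, MSX2 (0.63), TFAP2A (0.64) and NGFR (0.67), also did so. The medians were then 0.83 for the Nodal list and 0.44 for neuron. With a floor of 5 the retinoid median turned to -0.62. Of 30 lists with 3 or more genes, 13 lay outside the central 95% of random lists.

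The fourth comparison asked how TSA over days 4 to 8 altered the cells at day 8. Many metallothionein, neuron, REST target, neural crest, mesenchyme and WNT pathway genes rose with TSA, and some pluripotency, cholesterol synthesis and forebrain genes fell. All 6 metallothioneins above the floor rose, with a median of 3.57, MT2A from 2.49 to 7.62 and MT1E from 2.39 to 6.74. Of 15 neuron genes 8 rose, with a median of 1.31, STMN2 from 2.16 to 5.83 and GAP43, a growth cone protein, from 2.73 to 5.50, while NEUROG2 and STMN4 fell. Of 12 REST targets 7 rose and none fell, with a median of 1.36. VGF, a precursor of neuropeptides, went from 0.96 to 4.62. At a pseudocount of 5 the REST target median was 0.50, and CHGB (0.58), L1CAM (0.84), SNAP25 (0.90) and SYT4 (0.43) were below 2-fold. Of 8 neural crest genes 4 rose (MSX2 by 3.36, NGFR by 2.48, PAX3 and ETS1) and none fell, with a median of 1.43. PAX3 (0.84) and ETS1 (0.87) were below 2-fold with a pseudocount of 5. In the mesenchyme list 5 of 8 rose and TAGLN fell, with a median of 1.4998: COL1A1 went from 2.67 to 5.91 and COL1A2 from 2.99 to 5.80. Of 8 genes of WNT signalling 5 rose, the secreted inhibitor DKK1 by 2.61 and SP5 by 2.33, with a median of 1.07. With a pseudocount of 5 SP5 (0.99), RNF43 (0.58), TCF7 (0.53) and LEF1 (0.50) were below 2-fold, which left DKK1. The median was then 0.52.

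The forebrain and eye field list moved both ways, with a median of -0.52 over 11 genes. HESX1 fell from 6.42 to 2.96, SIX3 from 6.40 to 3.78 and RAX from 4.996 to 3.28, whereas EMX2, a homeobox gene of the cortex, rose from 0.08 to 2.89 and OTX1 also rose. In the neural progenitor list NCAM1 (1.56 to 4.13), POU3F2 (0.12 to 2.51), ZIC1 and CDH2 rose and MSI1, ZIC2 and POU3F1 fell, with a median of 0.26 over 15 genes. GBX2, which marks the anterior hindbrain, rose by 3.08 and FGF8 fell by 1.69 (median 0.18 over 4 genes). Of 18 pluripotency genes POU5F1 (by 1.81), L1TD1 (by 1.33) and DPPA4 fell and none rose, with a median of -0.43. The difference of NANOG was -0.98. FOXH1 fell by 3.05 and TDGF1 by 1.80 in the Nodal and activin list, whose median over 3 genes was -1.80. In the retinoid list CRABP1 rose from 6.93 to 9.75, ALDH1A2, CYP26B1 and RARB also rose, and CYP26A1 (by 3.16) and DHRS3 fell, with a median of 0.96.

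Of 11 cholesterol synthesis genes 5 fell and none rose, INSIG1 by 1.71, with a median of -0.76. Of 11 genes of the histone deacetylase inhibitor response CLU (by 2.08), HIST1H1C and GADD45B rose, with a median of 0.87, and CDKN1A differed by 0.98. The histone acetyltransferase genes KAT7 and KAT2A fell (median -0.55 over 9) and HDAC7 fell (median -0.31 over 11 histone deacetylases). None of the 20 cell cycle genes was called, with a median of -0.36. ASNS, DDIT3 and CHAC1 fell and TRIB3 rose in the endoplasmic reticulum stress list (median -0.19), and CHAC1, at -1.03, was just below 2-fold (-0.998) with the median of all genes set to 0. BAMBI rose by 2.02 among BMP signalling genes (0.47) and EGR1 by 1.68 among FGF and ERK genes (0.08). Among Notch genes (0.42) JAG1 rose by 2.30 and HEYL by 1.04, and DLL1 fell by 1.17. SLC1A3 and S100B rose and 1 gene fell in the glia list (-0.24). HAND1, CGA and GATA3 rose among 7 trophoblast genes (0.59), but with a pseudocount of 5 they differed by 0.97, 0.80 and 0.43, below 2-fold. KRT19 rose and EPCAM fell in the surface ectoderm list (0.34), CXCR4 rose and HHEX fell in the endoderm list (0.25), PDGFRA rose in the mesoderm list (0.19), MAGEA4 rose and DAZL fell in the germline list (0.58), and KDR rose by 2.21. FOS and EGR1 rose in the immediate early list (-0.31), BBC3 and PMAIP1 fell in the p53 list (-0.10), PFKP rose in the glycolysis list (0.26) and B2M rose in the housekeeping list (-0.23). The values in parentheses are list medians.

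With TSA at day 8, 1073 genes rose and 639 fell among 14040. With a pseudocount of 5 the counts were 344 and 310, and with one of 0.1 they were 1682 and 1018. Of the 101 called list members 43 differed by less than 2-fold with a pseudocount of 5, when the neuron median was 0.40, and GADD45B (0.96), HEYL (0.99) and PMAIP1 (-0.95) did so with the GC trend removed. Beyond the lists, DPPA5 (0.74 to 5.83), the nitric oxide synthase gene NOS2 (0.70 to 5.48) and SPP1 (1.04 to 5.23) rose, and HES3 (6.62 to 1.73), IDO1 (4.65 to 0.78) and TRIM22 (4.38 to 1.30) fell. WLS and PLEKHM1P among the 6 largest increases and H19, C7orf43 and LINC00599 among the decreases hold a microRNA. Of 28 lists with 3 or more genes, 15 lay outside the central 95% of random lists. The Spearman correlation of the difference with transcript length was -0.04 and with GC content 0.06.

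**Figure D2:**
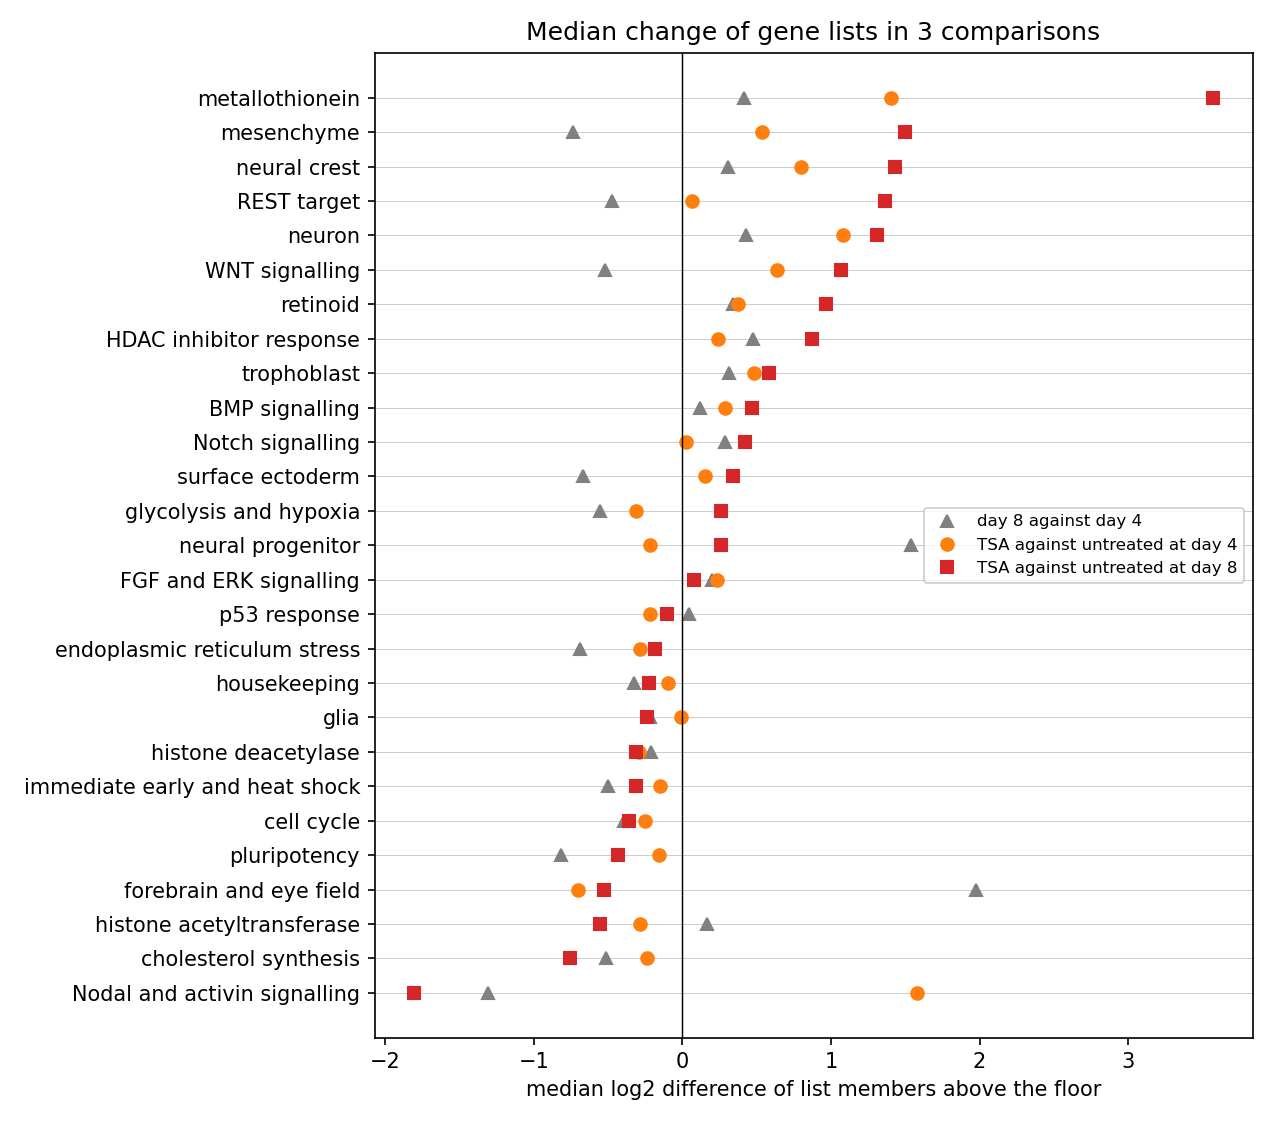
Median log2 difference (horizontal axis) of the members above the floor of each fixed gene list with at least 3 such members in all 3 comparisons (vertical axis, ordered by the TSA effect at day 8). Grey triangles are day 8 against day 4, orange circles TSA against untreated at day 4 and red squares TSA against untreated at day 8. The metallothionein list stood at 1.41 and 3.57 with TSA at day 4 and day 8, and the Nodal list at 1.58 and -1.80.

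The TSA effects in the 2 windows, which share no library, went together across genes. Both TSA libraries also differed the same way from both untreated ones of days 4 and 8 in small RNA and ribosomal protein genes. Small RNA rows listed at 0 numbered 157 and 146 with TSA and 114 and 115 without. Ribosomal protein medians were 10.56 and 10.40 with TSA and 10.71 and 10.75 without. Whether a difference between libraries shared by the TSA samples adds to the correlation was not tested. Over 13091 genes above the floor in both, the Pearson correlation of the log2 differences was 0.34 and the Spearman correlation 0.50. Among them 198 genes rose in both windows, against 20.6 for independent lists, and 91 fell in both, against 8.48. Genes that rose at day 4 and fell at day 8 numbered 20 (13.97 for independent lists), and 24 did the reverse (12.5). Without small RNA genes and genes that hold one, the Pearson correlation was 0.60, 169 genes rose and 51 fell in both, and 3 went opposite ways: FGF8 and BCYRN1 rose at day 4 and fell at day 8, and NRF1 did the reverse. BCYRN1 is named after its values had been seen. DPPA5, the metallothioneins, STMN2, MSX2, HAND1, KDR, B2M and MAGEA4 rose in both windows, and ASNS, CHAC1, CYP26A1, ZIC2 and MSI1 fell in both, MSI1 without the 2-fold call at day 4 once the GC trend was removed and CHAC1 without that at day 8 once the median was set to 0. A pseudocount of 5 ended the day 4 calls of MSX2 (0.63), HAND1 (0.79), MT1E (0.75), MT1F (0.93), MT1G (0.93), MT2A (0.95) and MSI1 (-0.83). It also ended the day 8 calls of HAND1 (0.97) and CHAC1 (-0.60).

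**Figure D3:**
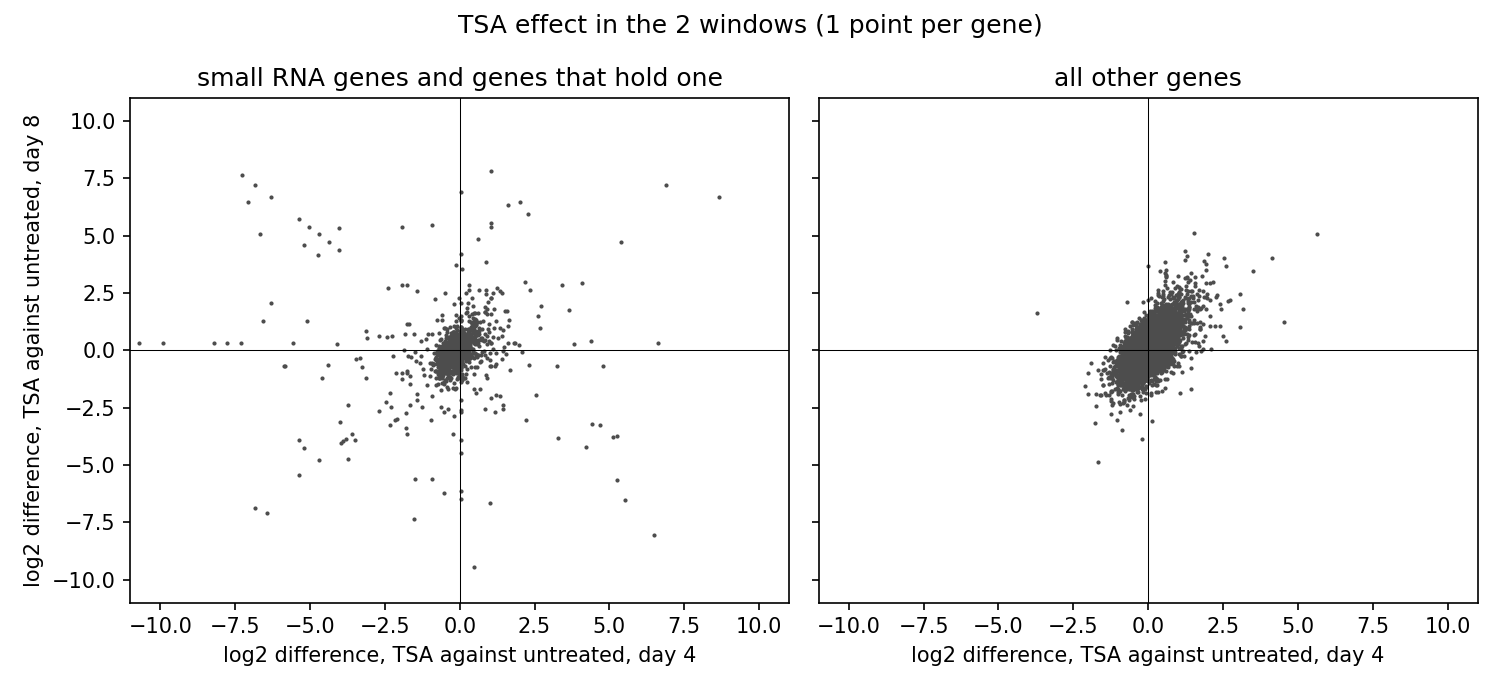
Log2 difference of TSA against untreated at day 4 (horizontal axis) and at day 8 (vertical axis), with 1 point per gene above the floor in both. The left panel shows small RNA genes and genes that hold a microRNA or small nucleolar RNA, and the right panel all other genes, whose Pearson correlation was 0.60.

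Genes that differed by 2-fold over untreated differentiation were also followed under TSA. Genes 2-fold lower at day 8 than at day 0 had a median TSA effect at day 4 of 0.02 (95% interval over 2181 genes -0.00082 to 0.04), against -0.08 for matched random lists. With a floor of 5 the median was -0.02 against -0.11 for random lists, and with the median of all genes set to 0 it was 0.10 against -0.01. Genes 2-fold higher had a median of -0.17 (-0.19 to -0.14, 2012 genes), against -0.05, and of -0.03 against 0.0015 with the trend with GC content removed. At day 8, genes 2-fold lower at day 4 than at day 0 had a median TSA effect of 0.28 (0.24 to 0.32, 1434 genes), against -0.04 for random lists, with 264 of them higher and 34 lower by 2-fold. Genes 2-fold higher at day 4 than at day 0 had a median of -0.18 (-0.22 to -0.14, 1850 genes), against -0.07. These gene sets rest on the day 0 library, with the length trend and missing small RNAs given above.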

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

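The tests of a carry-over of day 0 cells and of a change of the cells at day 0 were chosen after the result was seen, and older symbols were added to the matching of genes that hold a small RNA after a first run of that test. Gene lists and genes named by the fixed rule were singled out here when the TSA effect was 2-fold or more at both days and in opposite directions, and the day 0 library was added because it stood apart. BCYRN1, outside that rule, also differed in opposite directions, by 1.07 and -1.86. With 1 library per group none of these differences between days was tested.

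The median of the Nodal and activin list was 1.58 with TSA at day 4 (6 genes) and -1.80 at day 8 (3 genes, with NODAL, LEFTY1 and LEFTY2 then at 0.80, 0.03 and 0.35 with TSA), so the medians rest largely on different genes. The tables argue against a trend with GC content as the whole cause, since the day 4 median was 1.74 after its removal. They also argue against day 0 cells left in the TSA culture for NODAL and GDF3: NODAL would need 39.1% of day 0 cells, while 43 other genes abundant at day 0 and over 8-fold lower at day 4 implied at most 17.2%, and GDF3 exceeded its day 0 value. For LEFTY1 and LEFTY2, which imply 4.98 and 2.52%, a small carry-over cannot be told apart from a change within the cells, because the other genes had a median of 1.21% with quartiles of -0.17 and 3.22%. A general delay of differentiation may contribute, since genes lower at day 8 than at day 0 had a median TSA effect of 0.020 at day 4 against -0.08 in random lists, but that shift is small beside 1.58, so it stays open how much of the Nodal median it accounts for.

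KIAA0226 differed by 4.67 at day 4 and by -3.27 at day 8, and NRF1 by -3.71 and 1.64. They belong to 81 genes, small RNA genes aside, that differed by over 8-fold in at least 1 of the 3 comparisons among the later libraries. A microRNA or small nucleolar RNA inside the gene could set such a value where its short, abundant reads are counted for the host: 21 of the 81 genes (25.9%) hold one, against a median of 7.41% in matched random lists (2.47 to 13.6%). This leaves 60 genes, NRF1 among them, that hold none on the same strand by this annotation. Small RNAs of other kinds or on the opposite strand were not counted, and the read type is not given. The explanation is therefore not settled for these genes. Of the genes that hold one, 26.7% (4 of 15, exact binomial 95% interval 7.79 to 55.1%) went the same way by 2-fold in the other TSA comparison. Among the rest it was 55.6% (30 of 54). A bound on these shares, set before the test, was narrowly met against a response to TSA shared by both windows. Such a response still stays open for the genes that hold one, because the interval over 15 genes is wide.

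FGF8 differed by 1.44 at day 4 and by -1.69 at day 8. It holds no small RNA by the annotation used here, and stood at 0.65 and 4.08 without TSA at day 4 and day 8 and at 2.08 and 2.39 with it. Its day 4 difference was 0.57 with a pseudocount of 5.

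The day 0 library lies apart from the other 4. Under-representation of short transcripts there may account for part of this, as the correlation of transcript length with the difference of day 4 from day 0 was -0.48 against 0.06 for day 8 against day 4, small RNAs were mostly listed at 0, and ribosomal protein genes were lower. A change of the cells between day 0 and day 4 cannot be told apart from it, since the design has 1 day 0 library and how each library was made beyond the shared protocol is not given in the sources used here.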

How the results depend on the processing

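Removing the trends with transcript length and GC content, and leaving out small RNA genes and genes that hold one, were chosen after the data had been seen. Of 113 list medians, 20 changed sign under at least 1 alternative, 11 of them at day 4 against day 0. The 1 of these that had been 2-fold or more was that of trophoblast markers at day 4 against day 0, which was 0.25 with no filter, where genes below the floor enter, and the largest of the others in size was 0.574. Of the called list members, 32 of 102, 24 of 62, 35 of 48 and 43 of 101 in the 4 main comparisons were below 2-fold with a pseudocount of 5. The counts of genes called depend on the threshold and the pseudocount by construction. They are given as higher and lower for day 4 against day 0, day 8 against day 4, TSA at day 4, TSA at day 8, and day 8 against day 0. With a pseudocount of 5 they were 1021 and 846, 169 and 210, 143 and 135, 344 and 310, and 1087 and 1287. With a fold of 4 they were 471 and 404, 122 and 87, 89 and 87, 231 and 135, and 606 and 593. With a fold of 1.5 they were 3514 and 3234, 1093 and 1687, 1018 and 973, 2312 and 2061, and 3684 and 4244. With a pseudocount of 0.1 they were 748 and 729 for day 8 against day 4, 725 and 357 for TSA at day 4, and 1682 and 1018 for TSA at day 8. With a floor of 5, 250 genes were higher with TSA at day 4 and 631 at day 8. Without small RNA genes and genes that hold one, 97 were lower with TSA at day 4. The other counts stayed within 1.5 times those reported.

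The median TSA effect at day 4 on genes lower at day 8 than at day 0 was -0.019 with a floor of 5, 0.10 with the median set to 0, 0.087 with trimmed mean scaling, 0.14 with the length trend removed and 0.061 with the GC trend removed. On the higher genes it was -0.14 with no filter, -0.20 with a floor of 5, -0.094 with the median set to 0, -0.11 with trimmed mean scaling, -0.10 with the length trend removed and -0.035 with the GC trend removed. At day 8 the effect on genes lower at day 4 than at day 0 was 0.35 and 0.19 with pseudocounts of 0.1 and 5, 0.20 with a floor of 5 and 0.37 with the length trend removed. The correlation between the TSA effects was 0.32 with either pseudocount, 0.28 with no filter, 0.27 with a floor of 5, 0.36 with the GC trend removed and 0.60 without small RNA genes and genes that hold one. Beyond what the settings' construction gives, the cause was not tested. Depth is unknown, so what it limits cannot be stated for any gene.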

Other observations

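All groups of this part were chosen after the data had been seen. Of 9 lens crystallin genes 7 rose with TSA at day 4, with a median of 1.73, CRYBA1 from 0.22 to 2.80 and CRYBB1 from 1.42 to 3.15. CRYAA and CRYBA2 stood at 3.15 and 1.33 with TSA and were listed at 0 without. At day 8 none of the 5 crystallin genes above the floor was called, with a median of 0.40. The difference between the days was not tested.

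Of 10 genes linked to the naive or early pluripotent state above the floor, 4 rose with TSA at day 4 (DPPA5, NLRP7, KLF5 and KHDC3L, median 0.55) and 7 rose at day 8 (median 1.03), where ALPPL2 went from 3.02 to 6.85, ALPP from 1.38 to 4.77, and DPPA3 fell by 1.92. With the GC trend removed SUSD2, 1 of the 7, was at 0.96 and no longer called. Among genes of serine, glycine, proline and asparagine synthesis and other targets of ATF4, 5 of 11 fell at day 4, with a median of -0.92, among them PHGDH by 1.16 and PYCR1 by 1.08 (-0.80 with the GC trend removed, which ends its call), and 3 fell at day 8, with a median of -0.75, where SLC7A11 rose by 2.35. Of 8 imprinted genes 4 rose without TSA from day 4 to day 8 (median 1.18), DLK1 by 5.17, MEG3 from 0.53 to 3.16 and MEST from 5.63 to 7.04. H19, MEG3 and MEST hold a microRNA. With TSA at day 8 H19, DLK1 and MEST fell and PEG10 rose by 1.69, with a median of -0.70. Among Frizzled and secreted Frizzled-related genes, SFRP1 and FZD2 fell and FRZB rose with TSA at day 4 (median -0.33 over 12, and FZD2 at -0.93, no longer called, with the GC trend removed), and 4 of 13 fell and 1 rose at day 8 (median -0.24), where FZD5 went from 6.64 to 3.97.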
